A study of Mus musculus with 2 samples.

How the data were processed

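Gene expression was measured on Affymetrix Mouse 430 oligonucleotide arrays, on which each transcript is read by one or more probe sets of short DNA probes and biotin-labelled RNA is detected by its brightness. There were 2 arrays, 1 from Atf4 knockout cells and 1 from wild-type cells. Both held LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction that contains haematopoietic stem cells and early progenitors, sorted from mouse fetal liver at 15.5 days of development. Per the labels, the cells were primary, received no doxycycline, and had their total RNA extracted with TRIzol. The labels do not say how many embryos went into either sort.

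The deposited table holds 1 linear intensity per probe set and array, for 45037 probe sets. The software that summarised probes into probe sets, the background correction and the normalization are not given in the sources used here. The deposited intensities ran from 1.93 to 17588 on the knockout array and from 1.88 to 15941 on the wild-type array. Their medians were 35.6 and 35.9, and their 75th percentiles 148 and 151. Whether the authors scaled the arrays to each other is not given in the sources used here. Within an array, 7.48% of the knockout values and 7.84% of the wild-type values were exact repeats of another value. The table gave no detection calls, no standard errors and no Affymetrix control probe sets (0 identifiers of that type), so the planned check of RNA integrity and spike-in levels was not run.

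The intensities were taken as deposited and turned into log2(intensity + 13). The pseudocount of 13 was the 25th percentile of all values, rounded. All differences are knockout minus wild type on that scale, which understates the change of dim genes. The median difference over all probe sets was 0.01, so no further shift between the arrays was removed. Probe sets were named from GEO's platform annotation, with symbols updated through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 34945 carried 1 symbol, 932 several and 9160 none in that annotation. The symbol was updated or kept through the Entrez identifier for 34741 and kept from the annotation for 204. Only probe sets with 1 symbol were named. Each of 18193 genes was represented by its brightest probe set over both arrays. Of these, 11045 genes had a mean at or above the median of all probe sets (an intensity of about 35.7), and these are the genes meant by "measured" below. No genome build is named for the files, so no genomic positions are printed. The RefSeq table served only for gene names and to find which genes neighbour Atf4.

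With 1 array per genotype there is no replicate error, no test was possible, and no p-values are given. Descriptions of size took their place. A gene was counted as higher or lower when its difference reached 1 on the log2 scale with the pseudocount, called 2-fold in all counts. Counts at 1.5-fold use the same scale. Folds printed for single genes are ratios of deposited intensities, which the pseudocount does not shrink. A gene can therefore pass 2-fold in intensity without being counted, as Klhl4 did (2.13-fold higher, difference 0.93). Its difference was also ranked against the 500 measured genes nearest to it in mean level. In addition, each gene list was summarised by the median difference of its measured genes, and that median was placed as a percentile among 10000 random lists of the same size, matched on mean level over 20 level bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile, and lists with fewer than 5 measured genes were not placed. Genes of a real pathway are co-regulated and random genes are not, so a percentile describes these 2 arrays and is not a probability for the genotype. Probe sets of the same gene gave a measure of technical disagreement. Over 4965 genes with at least 2 probe sets above the level filter, the SD of the difference between probe sets of one gene was 0.18 on the log2 scale. Where the dimmer array lay under the median of all values (35.7), a fold is given as a lower bound against that median.

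The groups, the 29 gene lists and the 2 lists of sample checks, the size limits, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Atf4, then the 15 largest rises and 15 largest falls among measured genes, leaving out unnamed clones and genes with another probe set above the filter that went the opposite way or whose difference was under 0.5 times as large. It also named the 4 members of each list with the largest absolute difference, any member past 2-fold, and the sorting and sex-specific transcripts. Other list members given with a value, such as Mdm2, Mpo, Phgdh and Ddit3, and the genes named from the added lists were chosen after their values were seen. Of the list symbols, 72 matched no probe set with a single symbol and were not analysed here. Among them were Ly6a (Sca-1) and Angptl3. Of 569 measured genes in the 29 lists, 20 were in more than 1 list. A further 7 lists were written after the first results had been seen and are used only in the closing section. They hold further p53 targets, repressors of embryonic globin genes, neutrophil granule genes, complement C1q genes, MHC class II genes, eosinophil genes and genes of dendritic and monocyte precursors.

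The alternatives were quantile normalization, centring on the median of the probe sets above the filter, the mean of all probe sets of a gene, no level filter, a filter at the 75th percentile, pseudocounts of 1 and 36, removal of a lowess trend of difference on level (span 0.3), leaving out probe sets of the _x_at and _s_at types, a 1.5-fold limit, and 5 Mb in place of 10 Mb for the neighbours of Atf4. The counting and list procedures were tested on simulated data for the knockout against wild-type comparison, with 11045 genes given normal noise with the robust spread of the real differences in each of 20 level bins, which has lighter tails than the real values. Simulated lists were placed among 500 random lists. Of 200 genes changed 2-fold, 53.5% passed the 2-fold limit, and of 200 changed 3-fold or 200 changed 4-fold, 100% passed. Of the unchanged genes, 0 passed in any of these runs. Because fixed changes were added to noise narrower than the limit, these rates follow largely from the setting. The simulation holds no variation between embryos or cell preparations. Of 200 simulated lists of 20 genes, 5% stood apart with no shift, 64.5% with a shift of 0.1 and 99% with a shift of 0.2 on the log2 scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.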

Results

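The arrays compared LSK cells, the stem and progenitor fraction of blood-forming cells, from the fetal liver of Atf4 knockout and wild-type mice at 15.5 days of development, with 1 array each. ATF4 is a transcription factor that cells use to adapt to amino acid shortage and other stress. The design text names the purpose as finding the pathways of ATF4 in stromal and LSK cells, and the LSK arrays are those analysed here. Values without an error come from a single array per genotype, and the number of arrays limits the precision of every value below.

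Atf4 itself had the lowest knockout value relative to wild type of all measured genes. Its brightest probe set read 74.3 in the knockout and 1043 in the wild type, a 14.0-fold lower value (log2 difference -3.60), and 0 of the 500 genes nearest in level differed as much. A further probe set read 4.72 and 300.4, which is at least 8.41-fold lower because the knockout value lay under the median of all probe sets. The remaining one was dim on both arrays, at 18.3 and 15.6. The labels do not say which part of the gene was deleted, so the residual signal of 74.3 cannot be assigned to a part of the transcript.

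The remaining transcriptome differed little between the genotypes, and where it differed by 2-fold or more it was mostly lower in the knockout. Of 11045 measured genes, 8 were at least 2-fold higher and 35, Atf4 among them, at least 2-fold lower in the knockout on the scale with the pseudocount. At a 1.5-fold limit the counts were 51 higher and 119 lower. The central 95% of genes lay between -0.42 and 0.37 on the log2 scale, around a median of 0.02, and the log2 values of all probe sets correlated between the arrays with Pearson's r of 0.995 (across probe sets, which are not independent replicates). Among 3070 bright probe sets with no single gene name, 1 was 2-fold higher and 15 were 2-fold lower.

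**Figure D1:**
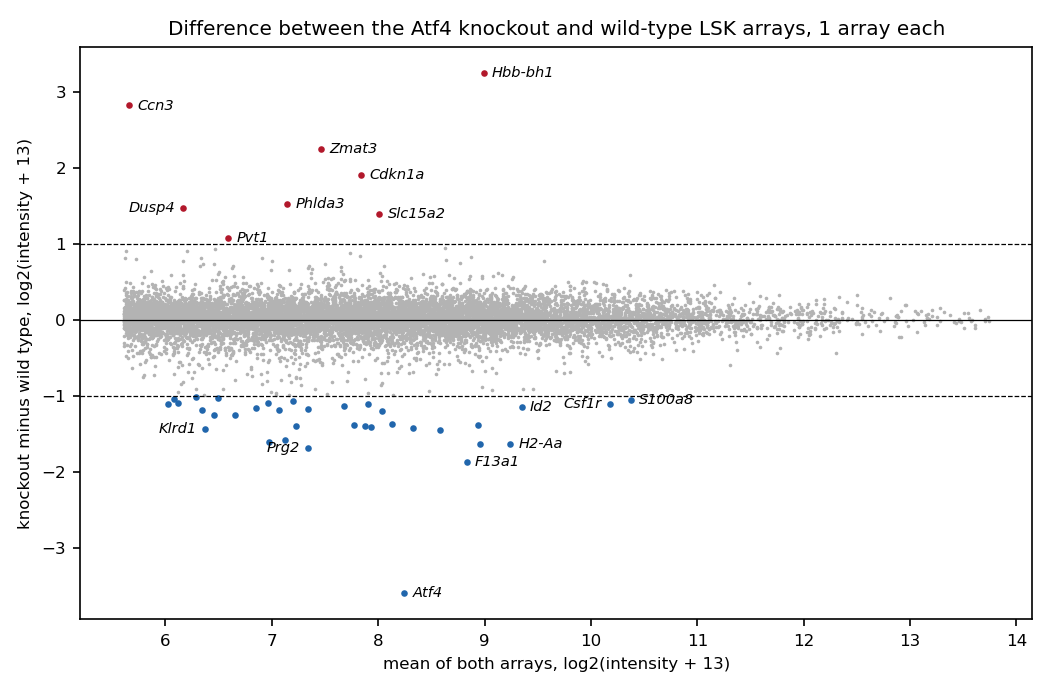
Difference between the arrays (knockout minus wild type, log2 scale with the pseudocount) against mean level for 11045 measured genes, 1 point per gene, with dashed lines at 2-fold on that scale. Red points are the 8 genes at least 2-fold higher in the knockout, from Pvt1 (1.07) to Hbb-bh1 (3.25), and blue points the 35 at least 2-fold lower, with Atf4 at -3.60.

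Genes known to be switched on by the tumour suppressor p53 were prominent among those higher in the knockout. Zmat3, an RNA-binding p53 target, read 371 against 67.6 in the wild type (5.48-fold, log2 difference 2.25). Cdkn1a, which encodes the cell cycle inhibitor p21, read 431 against 106 (4.08-fold, 1.91), and its other probe set above the filter differed by 1.40. Phlda3, an inhibitor of AKT signalling, read 228 against 70.3 (3.23-fold, 1.53). Ccng1, the cyclin G1 gene, was higher by 0.77 at its brightest probe set and by 1.06 at both of the others. Of 22 measured p53 targets, 15 were above and 7 below 0, 5 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. The fifth of these was Aen at 0.61, an apoptosis-enhancing nuclease. Other p53 targets stood near 0, including Mdm2, the ubiquitin ligase that acts on p53, at 0.07 (-0.54 at another probe set), Pmaip1 at 0.10 and Btg2 at -0.03. The list's median was 0.12, at percentile 98.7 of matched random lists, and its mean of 0.37 was carried by these few genes. Under the stricter level filter the median was 0.06 at percentile 81.0.

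Hbb-bh1, an embryonic beta-like globin gene, had the largest positive difference of all measured genes. It read 1554 in the knockout and 152 in the wild type (10.2-fold, log2 difference 3.25), and its other probe sets differed by 3.20 and 3.27. Hba-x, the embryonic alpha-like globin gene, was higher by 0.71. Hbb-y, a further embryonic beta-like gene of related sequence, differed by between -0.10 and 0.35 over its 3 probe sets, and the separation of such paralogs by short probes is uncertain. Erythroid and haem synthesis genes as a list did not stand apart. Of 23 measured, 11 were above and 12 below 0, and the median was -0.02 at percentile 18.9, while the mean was 0.14 because of Hbb-bh1. Within that list Cpox, a haem synthesis enzyme, differed by -0.70 at its brightest probe set and by 0.07 at another, and Epb42, a red cell membrane protein, by -0.30.

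Other genes among the 15 with the largest positive differences belonged to no fixed list. Ccn3, a secreted matricellular protein gene, read 121 in the knockout and 5.95 in the wild type, which is at least 3.38-fold higher. Dusp4, a MAP kinase phosphatase gene, read 107 and 30.1, at least 2.99-fold higher. Slc15a2, a peptide transporter gene, was 2.76-fold higher (log2 difference 1.39) and the non-coding RNA Pvt1 2.38-fold higher (1.07, with 0.59 at another probe set and 0.83 with their mean). Klhl4 (0.93), Ndnf (0.91), Unc45b (0.90), Gimap4 (0.84), Cox6b2 (0.83), Cdk18 (0.82) and Tjp1 (0.81) completed this group, each under 1 on the log2(intensity + 13) scale. Unc45b, with 23.1 in the wild type, lay under the median of all values there.

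Granulocyte and monocyte genes were lower in the knockout, with the lowest median of the 29 fixed lists. Of 21 measured genes of the myeloid list, 18 were below and 3 above 0, 10 were at least 1.5-fold lower and 4 at least 2-fold lower, with 0 at least 1.5-fold higher. The list's median of -0.45 was below those of all 10000 random lists (percentile 0), and with the stricter level filter it was -0.91. The 4 were Ly86 at -1.38, Elane (neutrophil elastase) at -1.38, Csf1r (the macrophage colony-stimulating factor receptor) at -1.10 and S100a8 (a calcium-binding protein of granulocytes and monocytes) at -1.06. Csf1r differed by -1.01 and -0.62 at its other probe sets and by -0.91 with their mean, which is under 2-fold. Smaller differences of the same sign were measured for Ms4a3 (-0.98), Irf8 (-0.92), S100a9 (-0.92), Ctsg (-0.90), Mpo (-0.44) and Spi1 (-0.45). Ngp at 0.56 and Ltf at 0.42, which encode proteins of the secondary granules of maturing neutrophils, lay in the other direction, and Cebpa, the regulator of granulocyte-monocyte fate, was at -0.11.

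The 15 genes with the largest negative differences were headed by Atf4. F13a1, the coagulation factor XIII A chain, read 226 in the knockout and 857 in the wild type (3.79-fold lower, log2 difference -1.86). Prg2, the eosinophil major basic protein, was 3.59-fold lower (-1.69). Ctss (cathepsin S) was 3.21-fold lower, Cybb (a subunit of the phagocyte NADPH oxidase) 3.49-fold, Lgals3 (galectin-3) 3.37-fold and Mpeg1 2.83-fold lower. Klrd1, Ms4a6c, Clec7a, Ctsh, Ly86, Elane, Apobec3 and Igsf6 differed by -1.43, -1.42, -1.41, -1.40, -1.38, -1.38, -1.37 and -1.26, the last falling under 2-fold (-0.99) with a pseudocount of 36. At their other probe sets above the filter, Cybb differed by -0.85 and Ctsh by -0.89, each under 2-fold. At most 3 of the 500 genes nearest in level differed as much as any of these 15 at their brightest probe sets. That rank follows largely from their choice as the largest negative differences. H2-Aa (-1.63) and Ccr2 (-1.40) were left out of the ranking because their probe sets disagreed, with differences of -0.46 for H2-Aa and -0.20 for Ccr2 at their least changed probe sets. Socs2, higher in the knockout by 0.94 at its brightest probe set and by between 0.23 and 1.12 at others, was left out of the positive ranking for the same reason.

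**Figure D2:**
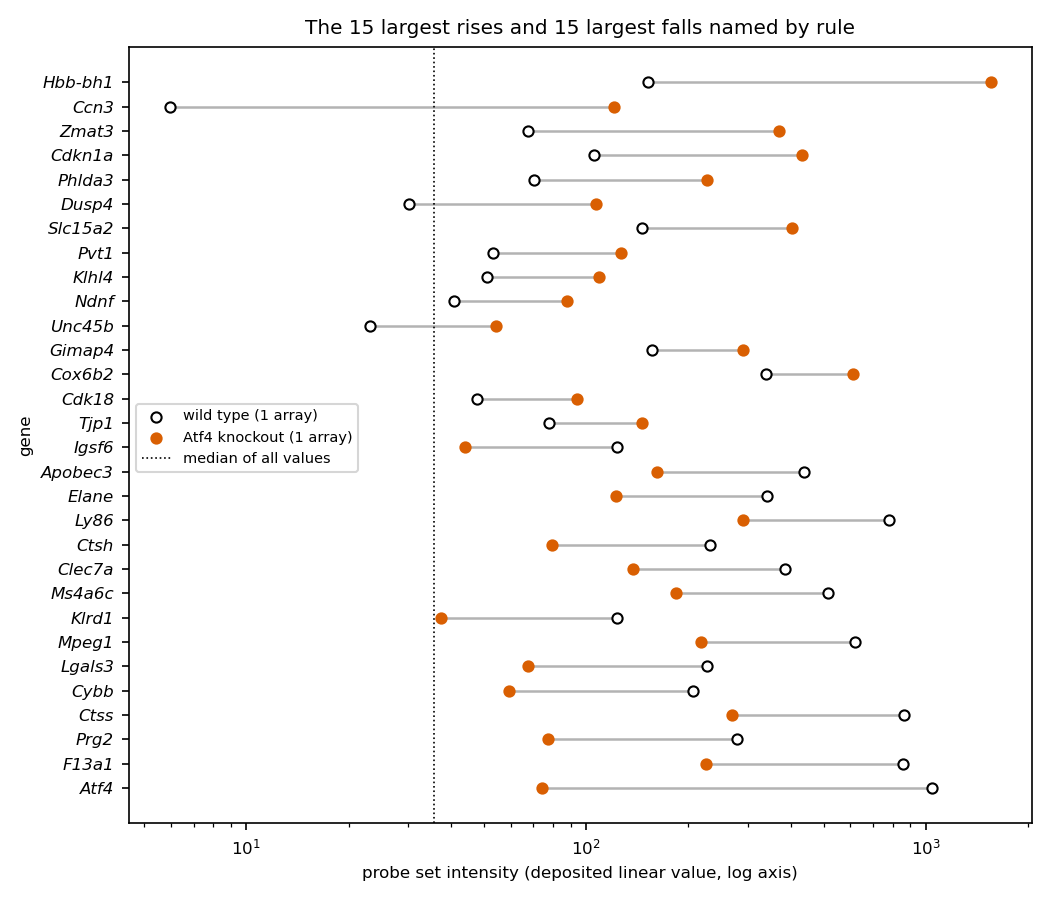
Deposited intensity (log axis) of the 15 largest positive and 15 largest negative differences in the wild-type array (open circles) and the Atf4 knockout array (filled circles), 1 array each, at the brightest probe set of each gene, with the median of all values (35.7) dotted. Atf4 read 1043 and 74.3, and the wild-type values of Ccn3, Dusp4 and Unc45b lie under the dotted line.

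Genes listed as markers of other fetal liver cell types also differed between the arrays, although some of them are also in the blood cell lists. Macrophage markers were lower, with 6 of 7 measured genes below 0 and a median of -0.25 (percentile 0.15), which was -0.07 over all members without a level filter and -0.15 with the mean of probe sets. That list shares Csf1r with the myeloid list, and Ctss was at -1.63, Cd5l at -0.56 and Slc40a1 at -0.25 (-0.03 at another probe set), while Vcam1 and Fcgr1, also measured, differed by 0.00 and -0.01. Hepatoblast and hepatocyte markers were lower in 8 of 10 measured genes, with a median of -0.19 (percentile 0.04), or -0.08 over all members without a level filter. Albumin (Alb) read 356 against 671 in the wild type, a difference of -0.89, and transthyretin (Ttr) differed by -0.99 (between -1.02 and 0.00 at its other probe sets), Apoa1 by -0.39 and Hnf4a by -0.33. Endothelial markers were higher in 11 of 14, with a median of 0.17 (percentile 99.7) that was 0.29 with the stricter filter, led by Cdh5 (VE-cadherin) at 0.73, Ramp2 at 0.49 and Tie1 at 0.40, whereas Robo4 was at -0.56. Mesenchymal stroma markers did not stand apart (median 0.05, percentile 65.0, 8 measured genes). Their largest differences were -0.33 for Pdgfrb (0.01 at another probe set), 0.20 for Col1a2, 0.17 for Acta2 and 0.14 for Sparc.

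Genes that mark haematopoietic stem cells were higher by small amounts in the knockout. Of 31 measured, 24 were above and 7 below 0, and the median of 0.13 stood at percentile 99.9. Procr (the endothelial protein C receptor, a stem cell surface marker) read 510 against 291 (1.75-fold, 0.78), Vwf (von Willebrand factor) was 1.82-fold higher (0.78) and the transcription factor gene Mecom 1.51-fold higher (0.59). Robo4 at -0.56 and Runx1 at -0.47 lay in the other direction. None of the 31 reached 2-fold. Robo4 and Esam are also in the endothelial list, whose median was higher too, at 0.17 (percentile 99.7). The fetal stem cell programme, with Igf2bp1 at 0.59, Igf2 at 0.58, Hmga2 at -0.23 and Peg3 at 0.22, did not stand apart (median 0.10, percentile 93.5, 11 measured genes).

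Lymphoid and mast cell genes were lower, and megakaryocyte genes were mixed. Of 14 measured lymphoid genes, 12 were below 0 (median -0.15, percentile 0.07). Rag1 (V(D)J recombinase) was at -0.54, Il7r (the interleukin-7 receptor) at -0.53, Flt3 at -0.39 and Satb1 at -0.31 (between -0.77 and -0.65 at other probe sets), and the Rag1 value in the knockout lay under the median of all values. With the stricter filter the lymphoid median was -0.11 at percentile 4.04, which no longer stood apart, and with the mean of probe sets it was -0.22. Of 6 measured mast cell and basophil genes 4 were below 0 (median -0.22, percentile 0.06, and -0.14 without a level filter), led by Hdc (histidine decarboxylase) at -0.86, with Cpa3 and Mitf at -0.25 each and Srgn at -0.19. The megakaryocyte list did not stand apart (median -0.04, percentile 12.9). Its members ranged from Pf4 (platelet factor 4) at -0.92, Tubb1 at -0.56 and Itgb3 at -0.39 to Vwf at 0.78.

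Known ATF4 target genes of amino acid metabolism were lower in the knockout, by modest amounts. Of 16 measured genes of amino acid synthesis and uptake, 12 were below 0 and 2 at least 1.5-fold lower, and the median was -0.16 (percentile 0.02). Asns (asparagine synthetase) read 244 against 480 (1.97-fold lower, -0.94), with -0.91 at its other probe set. Mthfd2 (mitochondrial folate enzyme) was 1.65-fold lower (-0.69) and Aldh18a1 (proline synthesis) 1.41-fold lower (-0.49). The serine synthesis genes Phgdh, Psat1 and Psph differed by only -0.19, -0.10 and -0.05, and Slc1a5, a glutamine transporter, was at 0.39, with -0.16 at another probe set. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower in 13 of 19 genes, with a median of -0.23 (percentile 0) that was -0.14 with the stricter filter. Cars was 2.30-fold lower (-1.03) at its brightest probe set but only -0.17 at another, and under 2-fold with quantile normalization or centring. Aars (-0.69), Iars (-0.58) and Yars (-0.57) followed, and Wars (0.23) and Eprs (0.14, between -0.18 and -0.12 at other probe sets) lay above 0.

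Of 20 measured stress regulators known to act downstream of ATF4, 13 were below 0 and the median was -0.09 (percentile 0.63), or -0.15 with the stricter filter. Herpud1 was at -0.43, Rab32 at -0.38, Nars and Jdp2 at -0.34, and none reached 1.5-fold. Nars, a tRNA synthetase gene, is also in the synthetase list. Ddit3 (CHOP, a stress-induced transcription factor) was at 0.04, Trib3 at 0.11 and Sesn2 at 0.27. Genes of the unfolded protein response of the endoplasmic reticulum were below 0 in 18 of 24 (median -0.10, percentile 0.07, and -0.05 with the mean of probe sets). Edem1 was at -0.45, Dnajc3 at -0.37 (between -0.27 and -0.07 at other probe sets) and Xbp1 at -0.30, while Pdia6 was at 0.37. Cholesterol synthesis genes were below 0 in 14 of 20 (median -0.09, percentile 1.27, and -0.14 with the stricter filter), with Nsdhl at -0.34, Sqle at -0.31, Idi1 at -0.25 and Dhcr7 at -0.21.

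Mitotic genes were lower and DNA replication genes were not. Of 31 measured genes of G2/M and mitosis, 26 were below 0, with a median of -0.17 (percentile 0). The mitotic kinesin Kif20a was at -0.39, Anln at -0.38, Cenpe at -0.30 and Mki67 at -0.29, and Cdk1 (0.24) and Birc5 (0.22) lay above 0. None reached 1.5-fold. The G1/S and DNA replication list was centred at 0.01 (percentile 38.7), with Pcna at 0.33, Ccne2 at -0.22, Tk1 at 0.20 and Rfc3 at 0.19. Apart from Cdkn1a at 1.91, no measured inhibitor of the cell cycle was 1.5-fold higher. Their list had 12 of 18 genes below 0 (median -0.06, percentile 4.16, mean 0.02), with Ccng2 at -0.43, Mxd4 at -0.41 and Cdkn2c at -0.27.

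Ribosome biogenesis genes were higher in 25 of 28, with a median of 0.15 above those of all 10000 random lists (percentile 100). The nucleolar factors Noc4l (0.49), Ebna1bp2 (0.44), Nop16 (0.30) and Nop2 (0.29) led, and none reached 1.5-fold. Ribosomal protein genes did not stand apart (median 0.04, percentile 84.9), with differences of 0.20 for Rps25, 0.19 for Rps19 and Rps9 (0.30 for Rps9 with the mean of probe sets), and 0.15 for Rplp0. Oxidative phosphorylation (median 0.06, percentile 94.5) included Ndufs1 at 0.44, Ndufs3 at 0.38, Sdhb at 0.36 and Cyc1 at 0.27. Glycolysis and hypoxia response (0.07, percentile 91.9) included Slc2a3 at 0.46, Tpi1 at 0.23, Pgam1 at 0.20 and Kdm3a at -0.16. Antioxidant genes (0.01, percentile 47.7) included Gpx4 at 0.34 (0.05 at another probe set), Txnrd1 at 0.32 (but between -0.76 and -0.55 at its other probe sets), Gsta4 at -0.30 and Srxn1 at 0.28. Autophagy genes were centred at 0.00 (percentile 33.8, mean of opposite sign), with Gabarapl1 and Wipi1 at 0.30, Atg12 at -0.29 and Atg10 at -0.19.

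Receptors for signals of the stem cell niche were below 0 in 22 of 31 measured genes, with a median of -0.10 (percentile 0.10). Il6ra was at -0.69 (with -0.03 at another probe set), Cxcr4 (the CXCL12 receptor) at -0.57, the prostaglandin receptor Ptger4 at -0.54 and Itgb3 at -0.39, whereas Kit was at 0.13. Immediate early genes did not stand apart as a list (median -0.04, percentile 6.61). Klf4, a transcription factor also used in monocyte development, was 2.48-fold lower (-1.18), and Egr1 (-0.70), Fos (-0.51) and Junb (-0.45) followed. The interferon response list had a median of -0.05 (percentile 3.42, mean 0.01), with Bst2 at 0.48, Gbp3 at -0.39, Ifit1 at 0.38 (under the median of all values in the wild type) and Ifitm3 at 0.36.

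In all, 12 of the 29 lists stood apart on the lower side and 4 on the higher side, where about 1.45 would be placed outside the limits by chance if genes were independent. The 4 higher lists were the endothelial markers, ribosome biogenesis, stem cell identity and p53 targets.

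**Figure D3:**
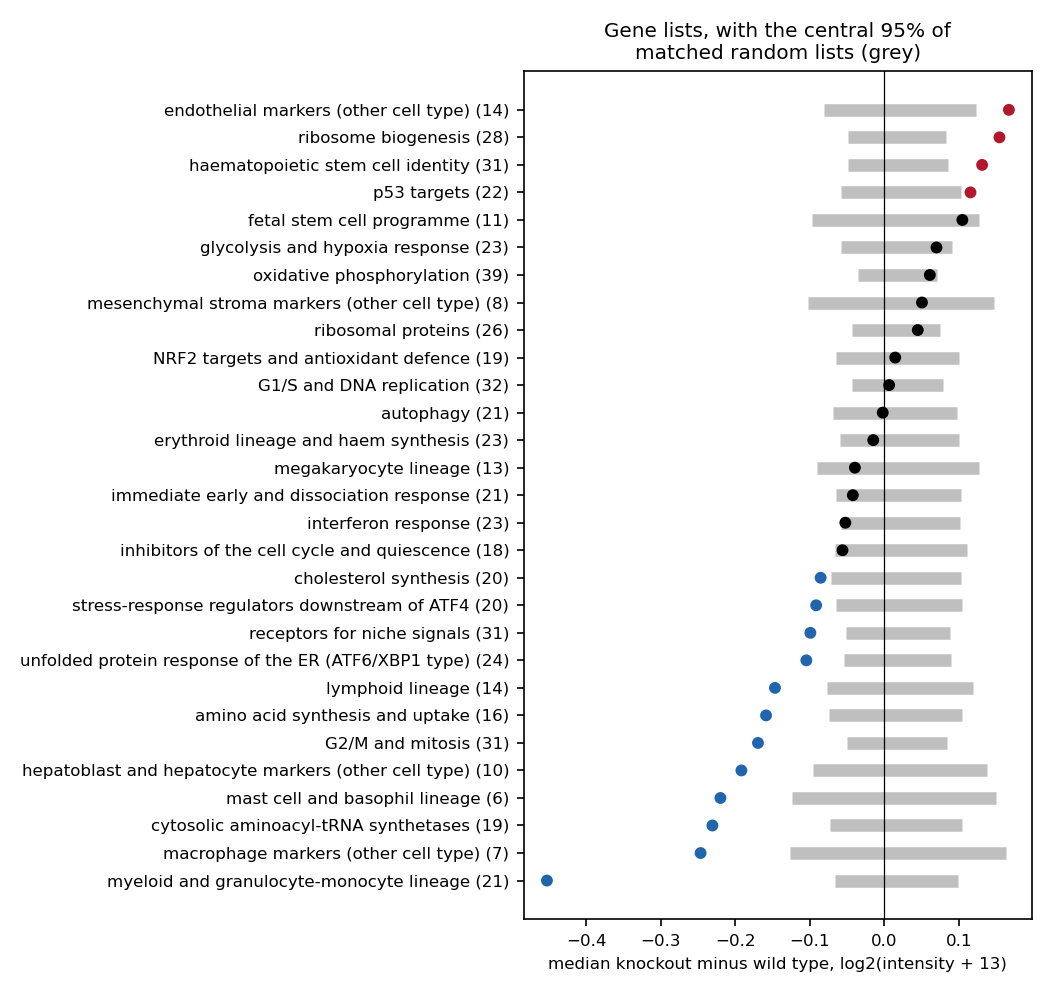
Median difference (knockout minus wild type, log2 scale) of each of the 29 gene lists, with the number of measured genes in parentheses and the central 95% of medians of 10000 level-matched random lists as grey bars. Blue and red points are the 12 lists below and the 4 lists above the limits, from the myeloid list at -0.45 to the endothelial list at 0.17.

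Transcripts used to check the samples were compared on both arrays. The sorting markers had a median difference of -0.02 at percentile 27.8 over 6 measured genes. These genes mixed Kit, Ptprc and Ptprcap with lineage markers that a gate can remove. Opposite differences can cancel in such a median, so it does not show whether the sorts were equally pure. Kit, part of the sorting gate, read 2366 in the knockout and 2154 in the wild type (another probe set differed by -0.36), and Ptprc (CD45) read 2361 and 2511 (-0.22 at another probe set), while Ptprcap differed by 0.05. Among lineage markers that a lineage gate can remove, Itgam (CD11b) read 40.8 and 82.4, Cd4 60.9 and 67.5, and Cd8a 40.5 and 36.7, and Cd3e and Cd5 were under the median of all values on both. Xist, transcribed from the inactive X chromosome, read 4049 and 4088, and differed by between -0.45 and -0.16 at its other probe sets. The Y-linked genes Kdm5d and Eif2s3y read 70.6 and 69.9, and 52.1 and 72.0, and Uty read 31.4 and 38.6.

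Genes near Atf4 on its chromosome were examined because a targeted allele can carry flanking DNA of another strain. If such DNA raised some genes and lowered others, their median would stay near 0, so the median cannot exclude it. The 204 measured genes within 10 Mb had a median difference of 0.05 at percentile 97.4, just inside the limit, and quantile normalization placed it outside at percentile 98.0. It was 0.03 at percentile 69.6 with the stricter filter, 0.03 at percentile 79.1 without a filter and 0.03 at percentile 94.0 with the mean of probe sets. With centring above the filter it was 0.07 at percentile 97.2. One of the genes within 10 Mb, Apobec3, an antiviral cytidine deaminase gene, was at least 2-fold lower (2.71-fold, -1.37), and 0 were at least 2-fold higher. Other than Atf4, 42 genes were past 2-fold in either direction, of which 0.776 would be placed within 10 Mb by chance. Apobec3 also lay within 5 Mb. Such a count cannot show whether its difference came from flanking DNA or from the loss of Atf4, which was not tested.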

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

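No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out in turn. The Atf4 transcript level differed by -3.60, and by -3.87 with the mean of its probe sets, -3.79 with a pseudocount of 1 and -3.29 with a pseudocount of 36, a shift built into those scales. The 8 higher and 35 lower genes became 4 and 17 with the stricter level filter, which tests fewer genes, and 51 and 119 with the 1.5-fold limit. The remaining settings gave 7 to 10 higher and 26 to 47 lower genes. Of the 16 lists that stood apart, 14 did so under each of the 9 alternatives that could be computed. The exceptions came with the stricter filter, where p53 targets had a median of 0.060 and the lymphoid list -0.11, both inside the limits. Lists that crossed the limit only under an alternative were glycolysis (0.099) and megakaryocyte genes (-0.069) without a level filter, immediate early genes (-0.073) with the mean of probe sets, cell cycle inhibitors with quantile normalization (-0.064) and without _x_at and _s_at probe sets (-0.085), and oxidative phosphorylation without those probe sets (0.095). The cause was not tested. The neighbours of Atf4 passed the limit with quantile normalization (0.057) and not within 5 Mb (median 0.04, percentile 88.4). With the stricter filter, the macrophage, hepatoblast, mast cell and mesenchymal lists had too few genes for a value. Of 852 values for 142 named genes under 6 alternatives, 810 moved by less than the probe set SD of 0.18, 42 moved further, each under another pseudocount or the mean of probe sets, and 4 genes changed sign: Txnrd1 (-0.33) and Kit (-0.11) with the mean of probe sets, Kdm5d (-0.01) with the lowess trend removed and Xist (0.01) with centring, the last at -0.21 with the mean of probe sets. What signal over background limits is the genes near the median of all values, where the pseudocount sets much of the difference.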

Other observations

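Several groups outside the fixed lists were looked at after the falls of single genes had been seen, so their genes were partly chosen for the pattern and the percentiles only describe its extent. MHC class II presentation genes were lower in the knockout in 8 of 8 measured genes, 7 of them at least 1.5-fold, with a median of -0.89 (percentile 0). Cd74, the invariant chain, read 159 against 322 in the wild type, H2-DMa 184 against 337 and H2-Eb1 105 against 188. Genes of dendritic and monocyte precursors had a median of -1.01 (percentile 0), with 8 of 14 at least 1.5-fold lower and 7 at least 2-fold lower, and 6 of the 14 are also in the fixed lists. Among them were the transcription factor genes Id2 (-1.15, with -0.73 at another probe set) and Irf8 (-0.92), while Tcf4 (-0.01), Fcgr1 (-0.01) and Cd7 (-0.09) differed by less than the probe set SD of 0.18 at their brightest probe sets. Of 4 measured eosinophil genes 4 were lower (median -0.76): Prg3 by a difference of -0.37, Siglecf of -0.44 and Prg2 of -1.69, and Epx at least 2.46-fold, since its knockout value lay under the median of all values.

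The tests on mature neutrophils, tissue macrophages, erythroid RNA, primitive erythroid cells and the preparation itself were chosen after the results had been seen. The 2 lists of further p53 targets and globin repressors were written before their percentiles were computed, although the values of at least 4 of the 33 measured further p53 targets (Mgmt, Gpx1, Ier5 and Notch1) and 2 of the 16 repressors (Bcl11a and Ikzf1) had already been seen. For each of the 3 patterns below, a difference between the cell preparations unrelated to genotype stays open, because there is 1 array per genotype. Markers of other cell types also differed between the arrays. The hepatoblast and hepatocyte list was lower in the knockout (median -0.19, percentile 0.04) and the endothelial list higher (median 0.17, percentile 99.7). Unequal carry-over of other cells into the 2 sorts was therefore not excluded.

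The lower granulocyte-monocyte genes may reflect fewer cells of those fates, or of their precursors, in the knockout gate, or lower expression in the same cells. Arrays of RNA from a whole sorted gate cannot tell these apart. Tissue macrophages carried over in the wild-type sort would bring complement C1q, and the brightest of C1qa, C1qb and C1qc there read 31.8, under the array median of 35.9, but these genes lay near the floor and the fixed macrophage list was lower (median -0.25, percentile 0.15), so they stay open. Mature neutrophils stay open too, since 3 of 6 granule genes above the median of all values on both arrays were higher and 3 lower (median 0.086, SD 0.57, and 0.10 over all 8 measured), from Hp at -0.98 to Ngp at 0.56. Monocytes and dendritic cell precursors were not excluded: a lineage gate with CD11b would remove monocytes that carry it, and Itgam, its gene, read 40.8 in the knockout and 82.4 in the wild type.

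For the higher p53 targets, a hypothesis is a p53-type response in the knockout cells. If it were broad, further targets would be expected to rise too. A second list of 33 measured targets had 22 genes above 0 and a median of 0.06 at percentile 89.0. Its largest positive differences at the brightest probe sets were Mgmt (0.71), Dcxr and Dglucy (0.49 each). Other probe sets of some members disagreed, with Sulf2 (-0.36) at 1.15 and Steap3 (-0.26) at 0.18. In the other direction, Tigar (0.30) lay between -0.08 and 0.04 and Ppm1d (0.02) at -0.15. The list neither met the bound set for such a response nor excluded it. The hypothesis stays open. In the first list, the targets at least 1.5-fold higher were Zmat3, Cdkn1a, Phlda3, Ccng1 and Aen, and Mdm2 was at 0.07. In the second list, 1 gene was at least 1.5-fold higher, namely Mgmt.

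The rise of Hbb-bh1 could come from erythroid RNA, from a few embryonic cells or from changed gene regulation. More of the erythroid RNA that both sorts hold is argued against, because 20 erythroid genes other than globins had a median of -0.021 and 75% of them lay below 0.11. A few primitive erythroid cells in the knockout sort stay open, since Hba-x was also higher by 0.71. Hbb-y did not rise at 2 probe sets (-0.10 and -0.09) and was higher by 0.35 at the other. Short probes may not separate it from its paralogs, so Hbb-y does not decide the question. Lower expression of repressors of embryonic globin genes was neither shown nor excluded: the 16 genes had a median of -0.05 at percentile 6.83, with Zbtb7a at -0.37, Sox6 at -0.31, Bcl11a at -0.18 and Kdm1a at 0.32. Other probe sets of Zbtb7a (-0.13 to 0.12), Sox6 (0.08) and Bcl11a (-0.03 to 0.19) went both ways or were higher.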
